A study of Arabidopsis thaliana with 4 samples.

How the data were processed

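Before the data were examined, the groups, tests, gene lists and alternative settings were written down from the sample labels. The series has 4 Agilent 4x44K Arabidopsis arrays on 1 slide, 2 for cyanamide at 2 h and 2 at 6 h. Every array has treated RNA in Cy5 and the 0 h control in Cy3, and there is no dye swap, so a dye bias of a gene stays in its ratio. Per the file headers the images were read with Feature Extraction 10.5.1.1, whereas the authors' notes give 8.5.1.1.

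The scanner files give mean signals, local background and processed signals as intensity, and flags as 0 or 1, as the authors deposited them. The deposited ratio of the scanner and the series value table are log10 ratios of Cy5 over Cy3, and the table is the scanner ratio rounded. They were turned to log2 for the alternative settings only.

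Values here were computed from the mean signals of 45220 spots, of which 1417 are control spots. Background was corrected by normexp with an offset of 50, and dye ratios were normalised by loess within each array, with control spots given weight 0. This assumes that ratios centre on 0 at each signal level. Replicate spots of a probe were averaged, giving 43603 probes, of which 37540 have 1 locus, 873 several and 5190 none. Probes with several loci or none were not tested. A probe was kept if well above background in 1 channel on both arrays of at least 1 time (31913 probes). The brightest probe stood for each locus, and 21073 genes were tested. A further 14 were left out because a spot was marked as an outlier. Of 28479 loci, 28074 were matched to the reference table (TAIR10.1), which was used for names only.

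Tests used limma 3.58.1 in R 4.3.3, with 1 fit over the 4 arrays, a mean per time and moderated t statistics (prior df 2.36, residual df 2). The 2 h and 6 h means were tested against 0. The spread of the controls enters only through the spread of the ratios between replicates. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Treated samples were set against the control on their own array. The SD given beside a mean is over the 2 arrays. The SE of a gene is from the fit, and the SE of a list median is over its members. Where the control was not well above background on both arrays, the fold is a bound: the treated mean against the mean, per array, of the higher of the control's own signal and the lowest signal among probes well above background. It equals the fitted fold where the control's own signal is the higher on both arrays. Bounds are open to dye bias.

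The 27 gene lists were fixed by locus code, and 435 of 449 members matched the reference by symbol. Each was tested with camera of limma, with a preset correlation of 0.01 between genes and again with a correlation estimated from the residuals, adjusted over the lists. The test with the estimated correlation has only the 2 residual df. At 6 h root markers had an estimated correlation of -0.0204, below the preset, yet adjusted p went from 0.000616 to 0.731. A call lost with it therefore does not show that correlation between genes made the shift. Since camera compares a list with all other genes, its direction can differ from the sign of the median. The lists are glutathione S-transferases, xenobiotic response, antioxidant enzymes, oxidative stress, heat shock, endoplasmic reticulum folding, sulfate assimilation, aldehyde dehydrogenases, jasmonate, ethylene, abscisic acid, auxin, expansins, cell division, DNA damage, morning clock, evening clock, photosynthesis, sugar starvation, hypoxia, touch, cold and defence, salicylic acid, phenylpropanoids, nitrate assimilation, nucleolus, root markers and reference genes.

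Genes named at each time are the 8 largest increases and 8 largest decreases among called genes with the same sign on both arrays and signal in both channels. To these come up to 3 per direction with a dim channel, and up to 4 members with the smallest p in each list that was called or had a called member. For 6 h minus 2 h the number was 5 per direction. Where none was called, the genes with the smallest p are given as values. Catalases and aldehyde dehydrogenases are always given. Not every gene under this rule is printed. Genes named as 2-fold on all 4 arrays were picked after their values were seen.

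The fit and the tests, without the normalisation, were tried on simulated log2 ratios of 21073 genes on 4 arrays, in 10 runs with 200 changed genes each. The spread of each gene was drawn from the fitted prior. A first version kept each gene's posterior SD from the real fit and was replaced after its output was seen. At 6 h a change of 1, 2 and 4 log2 units was called for 1.04%, 61.9% and 92.0% of genes, and 0.0254% of unchanged genes were called. For 6 h minus 2 h the shares were 0%, 4.18% and 76.8%. The trial of camera used 20 lists of 20 independent genes. In it, 10 of 10 shifted lists and 0 of 10 unshifted lists were called with either correlation. With the estimated correlation the lowest adjusted p in the trial was 0.0191. The trial does not show how often lists of correlated genes are called wrongly or missed, and the xenobiotic list had an estimated correlation of 0.959. The chance correlation from shared controls is the mean of 100 simulations.

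No untreated sample at 2 h or 6 h is given in the sources used here, so time of day was not analysed here.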

Results

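Transcript levels were measured in 14-day-old Arabidopsis thaliana Col-0 seedlings treated with cyanamide, a small nitrogen compound known to inhibit catalases and aldehyde dehydrogenases. The labels give a cycle of 16 h light and 8 h dark. Seedlings were lifted from agar, left for 1 h in 20 ml of water and then moved to 20 ml of water with 20 ppm cyanamide in the light. Seedlings collected at 0 h were the control, and treated seedlings were collected at 2 h and at 6 h, with 2 biological replicates per time. Each of the 4 dual-colour arrays carried a treated sample in Cy5 and a 0 h control in Cy3. The arrays of replicate 1 are taken to share a control RNA (control 1), and those of replicate 2 another (control 2). Their Cy3 signals were more alike within a replicate number than between numbers. The titles and treatment text name cyanamide, whereas the labelling text calls the Cy5 sample cis-CA-treated, so the identity of the compound rests on the former. Untreated seedlings were taken at 0 h only, and every ratio therefore holds cyanamide, elapsed time in water and time of day together.

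Signal was similar on the 4 arrays. The median spot signal was 347 to 396 in Cy3 and 412 to 497 in Cy5, over a local background of 43 to 45 and 59 to 61. Of 43603 probes, 28615 to 29502 were well above background in Cy3 and 31495 to 32157 in Cy5, and 0 spots were saturated. The 10 spike-in transcripts varied over the arrays with SDs of 0.04 to 0.23 log2, and all 10 were lowest on the 2 h replicate 1 array. On each array the scanner marked its spike-in slope, observed against expected, as out of range (0.802 to 0.822). Negative control spots had a median signal of 99.5 to 129.5 in Cy3 and 70 to 73 in Cy5.

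The 6 h replicates resembled each other and the 2 h replicates did not. Across 21073 genes, the log2 ratios of replicates correlated at r = 0.828 at 6 h and r = -0.142 at 2 h, and 81.8% and 46.7% of genes had the same sign on both arrays. The 2 h replicate 2 array correlated with the 6 h arrays at r = 0.589 and 0.652, and the 2 h replicate 1 array at r = 0.0642 and 0.00206. Genes are not independent replicates, so these correlations carry no p-value. The 2 control RNAs also differed. The SD of their log2 difference was 0.422, against 0.150 and 0.118 between the arrays that shared a control. Control 1 was at least 2-fold above control 2 for 447 genes and below it for 227. In control 1 the xenobiotic-response genes were higher by a median of 1.43 log2 (20 of 20 members), cytosolic heat-shock genes by 0.88 (8 of 8) and endoplasmic reticulum folding genes by 0.81 (8 of 8). Auxin-response genes (median -0.80) and cell-division genes (-0.67, with 0 of 22 members higher) were lower in control 1.

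**Figure D1:**
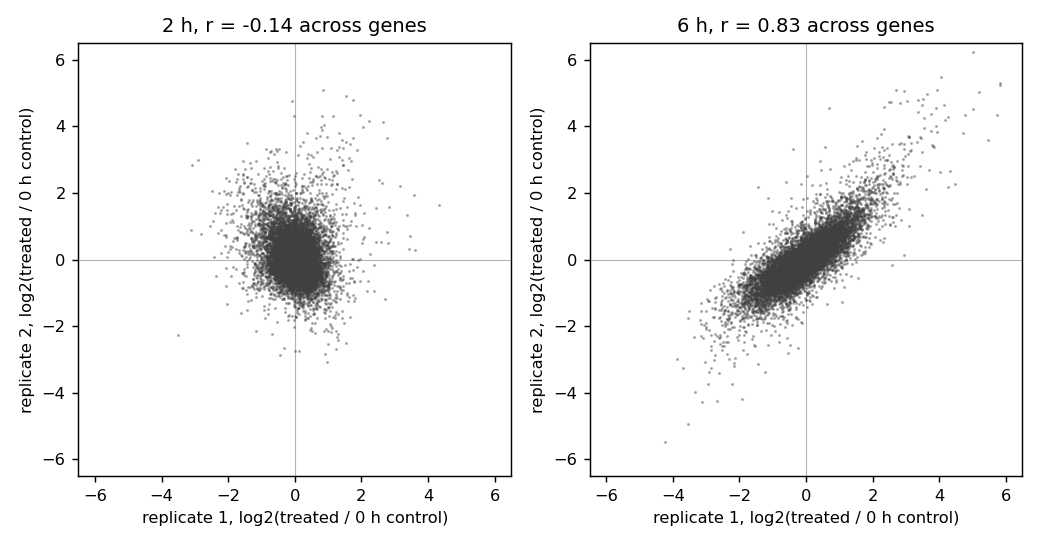
Log2 ratio of treated over 0 h control on the replicate 1 array against the replicate 2 array, at 2 h (left) and 6 h (right). Each point is a gene.

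The 2 h comparison asks which transcripts differ from control early in the treatment. The largest shift was in a list of 20 xenobiotic and electrophile-response genes, which encode glycosyltransferases, cytochromes P450, reductases and transporters that modify or export reactive compounds. These genes rose as a group: 19 of 20 were above control on both arrays and 0 were below, with a median log2 ratio of 2.15 (1.15 and 3.05 by replicate, adjusted p = 1.77e-16). With an estimated correlation between genes, adjusted p = 0.907. UGT75B1, a UDP-glycosyltransferase, had a log2 ratio of 3.39 ± 1.04 (SD, n = 2), OPR1, an oxophytodienoate reductase, 3.02 ± 1.37, UGT73C6 2.15 ± 0.79 and the NAC transcription factor ATAF1 1.79 ± 0.51. Adjusted over the list alone, 10 members passed, and over all genes 0 did. The same genes were 1.43 log2 higher in control 1 than in control 2, and their ratios were lower against control 1.

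Genes for glutathione conjugation and its sulfur supply also rose as groups at 2 h. Of 37 tau and phi glutathione S-transferases, 18 were above control on both arrays and 6 below (median 0.42, adjusted p = 9.74e-05, and adjusted p = 0.907 with an estimated correlation). GSTU2 stood at 1.67 ± 0.26, GSTU1 at 1.94 ± 0.94 and GSTU16 at 0.84 ± 0.06, and 3 members passed adjusted over the list alone. Without the 2 h replicate 2 array this list had a median of 0.25 and adjusted p = 0.107. Of 19 genes of sulfate assimilation and glutathione synthesis, 10 were above control on both arrays and 1 below (median 0.34, adjusted p = 0.000494, and adjusted p = 0.907 with an estimated correlation). APR3, an adenylylsulfate reductase, stood at 2.47 ± 0.10 (5.53-fold), SERAT2;1, a serine acetyltransferase, at 1.86 ± 0.95 and APR2 at 1.07 ± 0.12, and 3 members passed adjusted over the list alone.

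**Figure D2:**
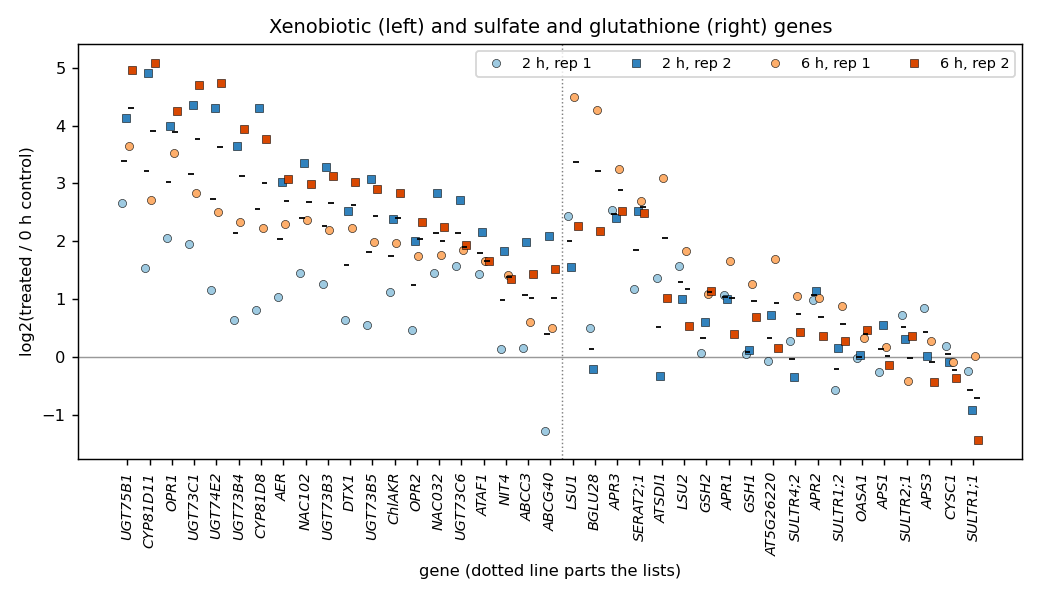
Log2 ratio to the 0 h control for xenobiotic-response genes (left) and sulfate and glutathione genes (right). Points are single arrays and black bars are the means of 2.

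A further 3 lists, of stress and secondary metabolism, rose at 2 h, and each lost its call in some settings. Of 23 jasmonate genes, 12 were above control on both arrays and 0 below (median 0.55, adjusted p = 1.99e-07, and adjusted p = 0.907 with an estimated correlation), among them the vegetative storage protein genes VSP1 (0.89 ± 0.02) and VSP2 (0.92 ± 0.10). Adjusted over the list alone, 2 passed, and without the 2 h replicate 2 array the median was 0.06 and adjusted p = 0.822. Phenylpropanoid and flavonoid genes had a median of 0.25 over 19 members (adjusted p = 0.00281, and adjusted p = 0.907 with an estimated correlation). PAP1, a regulator of anthocyanin genes, stood at 1.24 ± 0.28 and TT8 at -0.58 ± 0.01, while DFR was at least 1.86-fold above a dim control. Adjusted over the list alone, 3 were higher and 1 lower. The call ended with median centring (adjusted p = 0.524), a stricter filter (0.0609) and without the 2 h replicate 1 array (0.0745). Oxidative and mitochondrial stress genes had a median of 0.48 over 11 members (adjusted p = 0.0213, and adjusted p = 0.975 with an estimated correlation), but -0.25 on replicate 1 and 1.54 on replicate 2. The alternative oxidase gene AOX1A stood at 1.40 ± 1.33 and the mitochondrial protein gene OM66 (BCS1) at 0.90 ± 1.34. Median centring (adjusted p = 0.262) ended that call too.

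The 2 lists that fell at 2 h did so by little. Nucleolus and ribosome-assembly genes had a median of -0.31 over 8 members (adjusted p = 0.00728, and adjusted p = 0.975 with an estimated correlation), with NUC-L1, a nucleolin, at -0.58 ± 0.20 and the fibrillarin FIB2 at -0.57 ± 0.97. Their median was 0.18 with median centring (adjusted p = 0.823). Without the 2 h replicate 2 array adjusted p was 0.631. Root marker genes had a median of -0.18 over 16 members (adjusted p = 0.0330, and adjusted p = 0.907 with an estimated correlation), with the beta-glucosidase PYK10 at -0.65 ± 0.48 and the aquaporin TIP2;3 at 0.59 ± 0.09. With median centring their median was 0.22 (adjusted p = 0.870), and with the scanner's own ratios adjusted p was 0.0614. The call also ended without the 2 h replicate 2 array (adjusted p = 0.414), with a stricter filter (0.0609) and with each time fitted alone (0.0566). The other 19 lists had medians from -0.25 (nitrate and ammonium assimilation, adjusted p = 0.110) to 0.57 (heat shock, adjusted p = 0.149).

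For single genes at 2 h, limma called 0 of 21073 at adjusted p below 0.05 (lowest 0.6001). By unadjusted p below 0.05 there were 1399 (885 higher, 514 lower), where 1054 would pass by chance. SAG13, a senescence-associated oxidoreductase, stood at 3.204 ± 0.62 (9.21-fold), IAGLU, an indole-3-acetate glucosyltransferase, at 1.89 ± 0.01, PGL5 at 1.80 ± 0.22, AT1G75280 at 1.56 ± 0.02, AT1G19540 at 1.38 ± 0.20, UGT76E11 at 1.29 ± 0.14 and the iron-response regulator BHLH101 at 1.202 ± 0.04. Among genes with lower levels, those with the smallest p were AT1G26250 at -1.59 ± 0.01, AT1G67150 at -1.47 ± 0.06, AT2G36090 at -1.26 ± 0.06, AT5G54040 at -1.24 ± 0.29, AT5G60530 at -1.08 ± 0.11 and UGT72E2 at -0.98 ± 0.12. A further probe of AT1G26250 stood at -0.42 and of AT2G36090 at 0.10. By size alone, 104 genes were at least 2-fold from control on both arrays (95 higher, 9 lower), and 195 were 2-fold in opposite directions. Without the 2 h replicate 1 array the fit called 276 genes, with a variance taken from the 6 h arrays alone.

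The 6 h comparison asks which transcripts differ from control after longer treatment. Clock genes had one of the largest group shifts. All 8 afternoon and evening-phased genes were at least 2-fold above control on both arrays (median 2.66, 2.83 and 2.49 by replicate, adjusted p = 8.31e-09). With an estimated correlation adjusted p = 0.731. ELF4, a component of the evening complex, rose 34.4-fold (5.10 ± 0.11, SD, n = 2, adjusted p = 0.0255). Its partners LUX (PCL1; 3.87 ± 0.07, adjusted p = 0.0447) and ELF3 (2.02 ± 0.12, adjusted p = 0.0465) rose too, as did the pseudo-response regulator PRR5 (4.23 ± 0.46, 18.7-fold, adjusted p = 0.0490) and the blue-light receptor FKF1 (1.75 ± 0.07, adjusted p = 0.0465). Over all genes 6 of the 8 were called, and 8 passed adjusted over the list alone. Of 9 morning-phased genes, 8 were below control on both arrays and 1 above (median -2.05, adjusted p = 3.75e-05, and adjusted p = 0.731 with an estimated correlation). AT3G54500 (LNK2) fell (-2.05 ± 0.06, adjusted p = 0.0447), and RVE1 stood at -2.63 ± 0.66, RVE8 at -2.31 ± 0.58 and PRR9 at -1.34 ± 0.14. The difference between the controls was small beside these values, at 0.25 for the evening list and -0.34 for the morning list.

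**Figure D3:**
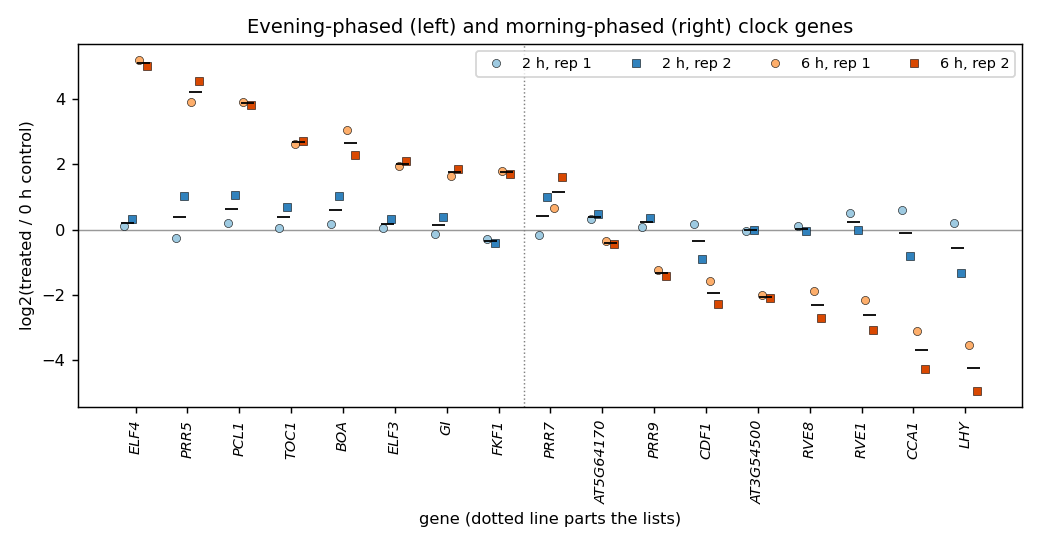
Log2 ratio to the 0 h control for evening-phased (left) and morning-phased (right) clock genes. Points are single arrays and black bars are the means of 2.

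Detoxification genes remained high at 6 h. All 20 xenobiotic-response genes were above control on both arrays, 18 of them at least 2-fold (median 2.64, 2.21 and 3.01 by replicate, adjusted p = 8.31e-09). With an estimated correlation adjusted p = 0.731. UGT75B1 stood at 4.30 ± 0.94 (adjusted p = 0.0527), OPR1 at 3.89 ± 0.51 (adjusted p = 0.0567) and ATAF1 at 1.66 ± 0.01 (adjusted p = 0.0556), and 0 members were called over all genes in this fit while 18 passed adjusted over the list alone. Glutathione S-transferases rose as a list (median 0.73, adjusted p = 0.00342, and adjusted p = 0.731 with an estimated correlation), with 24 of 37 above control on both arrays, 11 below and 14 at least 2-fold higher. GSTU25 (4.39 ± 0.35, 21.0-fold, adjusted p = 0.0465), GSTU19 (3.12 ± 0.44, adjusted p = 0.0472), GSTU22 (2.58 ± 0.03, adjusted p = 0.0490) and GSTU2 (2.54 ± 0.25, adjusted p = 0.0465) were called. Adjusted over the list alone, 16 were higher and 5 lower. Sulfate and glutathione genes rose (median 0.93, 1.101 and 0.43 by replicate, 14 of 19 above control on both arrays, 1 below, adjusted p = 0.000451, and adjusted p = 0.731 with an estimated correlation). APR3 rose 7.40-fold (2.89 ± 0.52, adjusted p = 0.0465), and SERAT2;1 stood at 2.59 ± 0.15 and GSH2, the glutathione synthetase, at 1.12 ± 0.03. Adjusted over the list alone, 6 passed. The controls differed by -0.23 for the sulfate list.

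The known enzyme targets of cyanamide were examined gene by gene. Among aldehyde dehydrogenases, ALDH5F1, the succinic semialdehyde dehydrogenase, rose at 6 h (2.06 ± 0.13, 4.17-fold, adjusted p = 0.0490). ALDH7B4 stood at 2.46 ± 0.17 (adjusted p = 0.0572), ALDH6B2 at 1.37 ± 0.14 and ALDH3F1 at -1.03 ± 0.47, and the 10 others lay between -0.40 (ALDH2B7) and 0.98 (ALDH2B4) without a call. The list as a whole had a median of 0.09 (adjusted p = 0.444), with 3 higher and 1 lower adjusted over the list alone. Of the catalases, CAT1 stood at 1.49 ± 0.24 (adjusted p = 0.0572), CAT3 at 0.48 ± 0.24 (adjusted p = 0.125) and CAT2 at -0.06 ± 0.09 (adjusted p = 0.753). With median centring CAT2 turned to 0.60 (adjusted p = 0.0429). At 2 h the catalases lay between -0.12 (CAT3) and 0.43 (CAT2) and the aldehyde dehydrogenases between -0.35 (ALDH2C4) and 0.95 (ALDH7B4), with 0 called. The wider antioxidant list was not called at 6 h (median 0.16, adjusted p = 0.138), but its member GPX6, a glutathione peroxidase, rose 13.5-fold (3.75 ± 0.29, adjusted p = 0.0490). DHAR2, a dehydroascorbate reductase, stood at 2.87 ± 0.02 (adjusted p = 0.0567).

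Genes of photosynthesis and growth fell as groups at 6 h. Of 24 nuclear photosynthesis genes, 14 were below control on both arrays and 1 above (median -0.65, -1.18 and -0.15 by replicate, adjusted p = 5.95e-05). With an estimated correlation adjusted p = 0.731. Rubisco activase, RCA, stood at -0.95 ± 0.05 (adjusted p = 0.0567), the small subunit RBCS2B at -1.47 ± 0.42 and the antenna gene LHCB2.1 at -1.80 ± 1.02. Without the 6 h replicate 1 array the call ended (adjusted p = 0.0747), and with median centring the median was 0.03, though the list stayed lower than other genes. Expansin and xyloglucan endotransglucosylase genes, which loosen cell walls, fell (median -0.83, 14 of 20 below on both arrays, 2 above, adjusted p = 0.00707, and adjusted p = 0.731 with an estimated correlation). EXPA1 stood at -2.09 ± 0.42, XTH4 at -1.98 ± 0.66 and XTH8 at -1.89 ± 0.45. Cell-division genes fell by little (median -0.38, 20 of 22 below on both arrays, 0 above, adjusted p = 0.00525, and adjusted p = 0.805 with an estimated correlation), with the D-type cyclin CYCD3;1 at -0.77 ± 0.69 and KNOLLE (SYP111) at -0.84 ± 0.05. Root markers fell (median -0.40, 11 of 16 below on both arrays, 0 above, adjusted p = 0.000616, and adjusted p = 0.731 with an estimated correlation), with TIP2;2 at -1.08 ± 0.06 and SCR at -0.91 ± 0.16. Adjusted over the list alone, 7 root markers, 2 photosynthesis genes, 0 expansins and 0 cell-division genes passed. The controls differed by -0.58 for the expansins and -0.67 for cell division, with control 1 lower. Against the mean of both controls the cell-division median was -0.74 on replicate 1 and -0.07 on replicate 2.

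Carbon-starvation and protein-folding genes rose at 6 h. Of 11 sugar-starvation genes, 10 were above control on both arrays and 1 below (median 1.32, adjusted p = 0.00342, and adjusted p = 0.731 with an estimated correlation). The dormancy-associated DYL1 stood at 1.85 ± 0.43, the asparagine synthetase ASN1 at 1.80 ± 0.13 and BT2 at 1.72 ± 0.93, and 4 passed adjusted over the list alone. All 8 endoplasmic reticulum folding genes were above control on both arrays (median 0.73, adjusted p = 0.0458, and adjusted p = 0.788 with an estimated correlation), led by the chaperone BIP3 at 2.46 ± 0.97. Without the 6 h replicate 2 array that call ended (adjusted p = 0.0757). The same 8 genes were higher in control 1 by 0.81. The hypoxia list was not called (median 1.202, 1.45 and 0.53 by replicate, adjusted p = 0.0547), though AT4G33070 (PDC1), a pyruvate decarboxylase, rose 4.42-fold (2.14 ± 0.19, adjusted p = 0.0465). PDC2 stood at 2.14 ± 0.14 and the haemoglobin gene HB1 at -1.15 ± 0.09. In the ethylene list (median 0.10, adjusted p = 0.911) ACS11, an ACC synthase, fell 3.52-fold (-1.82 ± 0.16, adjusted p = 0.0472), while ACS2 stood at 2.32 ± 0.43 (adjusted p = 0.136).

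Outside these lists, the largest called increases among genes with signal in both channels on both arrays were AT4G33980 (5.56 ± 0.37, 47.2-fold, adjusted p = 0.0289), the beta-glucosidase DIN2 (5.04 ± 0.99, adjusted p = 0.0495), SAG13 (4.76 ± 0.35, 27.2-fold, adjusted p = 0.0447), the transcription factor DREB2C (4.28 ± 0.01, adjusted p = 0.0490) and GLYI7, a glyoxalase (4.26 ± 0.66, adjusted p = 0.0472). The cold-regulated COR27 was at least 46.3-fold above a dim control (adjusted p = 0.0447), UGT76E12 at least 7.80-fold (adjusted p = 0.0447) and the peroxidase PRX52 at least 5.41-fold (adjusted p = 0.0490). The largest called decreases among such genes were AT3G28270 (-3.47 ± 0.31, adjusted p = 0.0447, with its other probes at -1.09 and below), AT2G15020 (-3.34 ± 0.57), the B-box genes BBX30 (-3.13 ± 0.33, adjusted p = 0.0465) and BBX16 (-2.89 ± 0.18, adjusted p = 0.0472), AT4G15430 (-3.06 ± 0.28), AT3G12320 (-3.01 ± 0.57), the plastid transporter gene PPT2 (-2.72 ± 0.51) and AT4G34810 (-2.72 ± 0.19, adjusted p = 0.0465). For AT2G15020, AT4G15430, AT3G12320 and PPT2 adjusted p = 0.0490. On the array design's coordinates (ath1:Jan2004) the ELF4 probe lies on chromosome 2 at 16741416 to 16741475 and the GSTU25 probe on chromosome 1 at 5872883 to 5872942. The SAG13 probe lies on chromosome 2 at 12609382 to 12609441 and the AT3G28270 probe on chromosome 3 at 10541007 to 10541066.

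In total limma called 133 of 21073 genes at 6 h (94 higher, 39 lower). By unadjusted p below 0.05 there were 6452 (3370 higher, 3082 lower). By size alone, 1322 genes were at least 2-fold from control on both arrays (743 higher, 579 lower), and 6 were 2-fold in opposite directions. The count depends on the settings: it was 0 with an intensity trend, at adjusted p below 0.01 or without either 6 h array, and 6110 with median centring. In simulated data with 200 changed genes per run, only 1.04% of genes changed by 1 log2 unit were called, so uncalled genes are not shown to be unchanged. That share depends on how many genes change, so it is not the sensitivity of the fit to the real data. UGT75B1, OPR1, CAT1 and ALDH7B4, given here without a call, were called in several other settings. The other lists at 6 h had medians of 0.42 for jasmonate (adjusted p = 0.0525), 0.60 for oxidative stress (0.172), -0.39 for auxin (0.138), -0.24 for nitrate assimilation (0.138), -0.21 for DNA damage (0.178), -0.13 for phenylpropanoids (0.322) and 0.40 for heat shock (0.457). Medians were 0.40 for touch, cold and defence regulators (adjusted p = 0.0968), 0.21 for reference genes (0.0968), 0.03 for salicylic acid (0.774), 0.08 for abscisic acid (0.824) and -0.08 for the nucleolus (0.824).

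**Figure D4:**
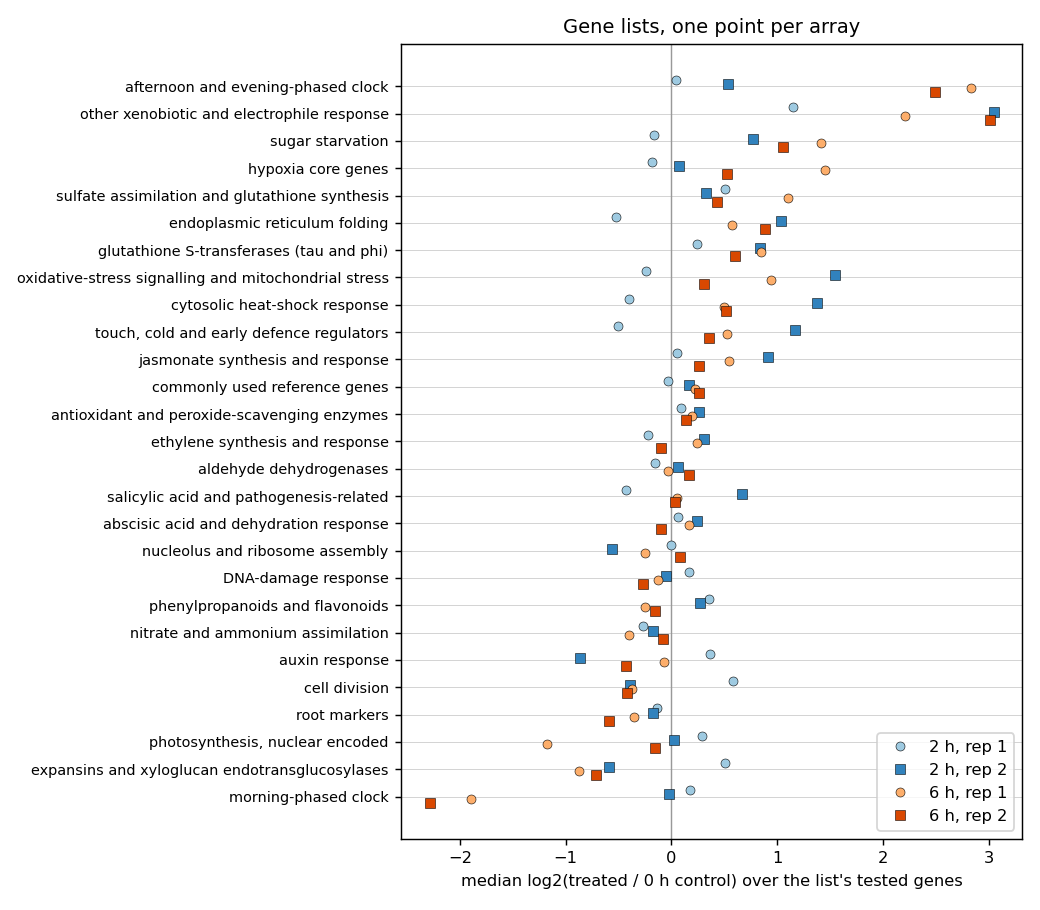
Median log2 ratio to the 0 h control of each of 27 gene lists, with a point for each array.

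The 6 h minus 2 h comparison asks what differs between the exposures, and a dye bias shared by all arrays drops out of it. Clock genes separated the times most. The evening list was higher at 6 h by a median of 2.199 (adjusted p = 2.81e-13, and adjusted p = 0.494 with an estimated correlation) and the morning list lower by -2.03 (adjusted p = 3.69e-08, and adjusted p = 0.494 with an estimated correlation). In each list 8 members passed adjusted over the list alone. ELF4 differed by 4.89 (SE 0.19, adjusted p = 0.138), AT4G33980 by 5.16 (SE 0.25, adjusted p = 0.179), LUX (PCL1) by 3.25, FKF1 by 2.097, RVE1 by -2.87 and BBX30 by -3.10. Photosynthesis genes were lower at 6 h (median -0.93, adjusted p = 2.96e-08, and adjusted p = 0.870 with an estimated correlation), with RCA at -1.07 and LHCB1.1 (CAB2) at -2.08. Phenylpropanoid genes were lower (median -0.37, adjusted p = 0.00399, and adjusted p = 0.494 with an estimated correlation), with F3H at -1.39 and PAL2 at -1.05, and 4 passed adjusted over the list alone. With a stricter filter that call ended (adjusted p = 0.129).

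The other 5 lists that differed between the times lost their call without the 2 h replicate 1 array. Cell-division genes were lower at 6 h (median -0.51, adjusted p = 0.000362, and adjusted p = 0.870 with an estimated correlation), as were expansins (-0.76, adjusted p = 0.00535, and adjusted p = 0.870 with an estimated correlation) and root markers (-0.44, adjusted p = 0.00406, and adjusted p = 0.494 with an estimated correlation). Sugar-starvation genes were higher (0.63, adjusted p = 0.0129, and adjusted p = 0.870 with an estimated correlation), as were hypoxia genes (1.13, adjusted p = 0.0161, and adjusted p = 0.870 with an estimated correlation), with PDC2 at 1.70 and SUS1 at 1.13. Without the 2 h replicate 1 array the medians were -0.05 for cell division (adjusted p = 0.827), -0.04 for expansins (0.866), -0.20 for root markers (0.071), -0.07 for sugar starvation (0.653) and 0.89 for hypoxia (0.100). The xenobiotic list differed by 0.61 (adjusted p = 0.142), glutathione S-transferases by 0.55 (0.118) and the sulfate list by 0.42 (0.0597), without a call. For single genes limma called 0 of 21073 (lowest adjusted p = 0.138), and 2137 had an unadjusted p below 0.05. AT1G17665 stood at 3.08, BBX8 at 2.66, AT5G42760 at -3.21, AT2G41250 at -2.79 and XTH33 at -1.93. A fit of the channels as separate samples, chosen after the data were seen, called 166 (111 higher, 55 lower).

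The 2 h and 6 h responses resembled each other in part. Their mean log2 ratios correlated at r = 0.584 (rho = 0.529) across genes, with a covariance of 0.123. Both times are taken to have used the same 2 control RNAs. Simulated data with shared controls and no response at either time gave r = 0.4999 and a covariance of 0.0357. That r is not the value for unrelated responses, which were not simulated. The covariance above the simulated covariance was 0.0872. Of genes with unadjusted p below 0.05, 569 were higher at both times and 338 lower at both. Independent lists would share 141.5 and 75.2, but these lists share their controls, and the overlap that shared controls alone give was not simulated. Without the 2 h replicate 2 array r was 0.0366. On all 4 arrays 63 genes were at least 2-fold above control, among them SAG13, UGT75B1, CYP81D11, DIN2, APR3 and the sulfur-deficiency genes LSU1 and LSU3. The 5 genes at least 2-fold below control on all 4 were the nitrate transporter gene NRT2.5, COR15A, the cytokinin-response regulator ARR6, CYP702A5 and AT5G54040.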

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

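The tests of explanations in this section were chosen after the result they concern was seen, apart from that of a noisy hybridisation. The tests of the lists and genes between the times were planned.

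The 2 h replicates were unlike while the 6 h replicates were alike. A noisy 2 h replicate 1 array may have caused this, which would give a low correlation between the 2 brightest probes of a gene on that array. That correlation was 0.856, against 0.892, 0.906 and 0.900 on the others, which argues against it. The difference between the control RNAs alone would also lower the 6 h correlation, which was 0.828 with the same controls. The 6 h ratios were more spread, however, with SDs of 0.722 and 0.640 against 0.413 and 0.560 at 2 h. The same control difference weighs less in them, so the 6 h correlation by itself does not exclude it. With the control difference alone, the 2 h treated samples would be alike. Their Cy5 levels differed with an SD of 0.410, against 0.150 and 0.118 between arrays that shared a control. Over genes, that difference correlated with control 1 minus control 2 at r = -0.619. Both values argue against the controls as the only cause. An exchange of replicate numbers between the 2 h treated samples remains open: with the controls exchanged the 2 h ratios correlated at r = 0.538, and at r = -0.128 with their own. The Cy5 difference between replicates ran opposite to the control difference at 2 h (r = -0.619) and the same way at 6 h (r = 0.638).

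Clock genes differed strongly between 6 h and 0 h. A dye bias common to all arrays could produce a shift, but each 6 h array lay above each 2 h array, by at least 1.96 in the median of the evening list, and 8 of 8 members did so. The controls differed by only 0.249 in this list, which argues against them as the cause. The direction, evening genes up and morning genes down, is what passage of the day alone would give, and this explanation of the 6 h median of 2.66 stays open. An untreated sample at 6 h would decide it.

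Xenobiotic genes were above control on every array. A control replicate low in these genes could cause this, but against control 1, the higher control, the lowest treated median was still 1.202. Its SE over members was 0.204, which treats them as independent, whereas their estimated correlation was 0.959. A dye bias as the whole cause would give equal ratios at 2 h and 6 h against the same control. The median difference was 1.22 in replicate 1 and -0.0464 in replicate 2 (SE over members 0.105 in each). The replicate 1 value is not what a dye bias as the whole cause would give, and the replicate 2 value is. The replicates disagree, so the test does not decide, and a dye bias stays open. Handling or elapsed time in water also stays open for the lowest array median of 1.15, since only 0 h controls were used.

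The lists that differed between the times were the evening clock (median 2.199, adjusted p = 2.81e-13), photosynthesis (-0.93; 2.96e-08), the morning clock (-2.03; 3.69e-08), cell division (-0.51; 0.000362), phenylpropanoids (-0.37; 0.00399), root markers (-0.44; 0.00406), expansins (-0.76; 0.00535), sugar starvation (0.63; 0.0129) and hypoxia (1.13; 0.0161). With an estimated correlation none of the 9 was called (adjusted p = 0.494 to 0.870), and cell division, root markers, expansins, sugar starvation and hypoxia also lost the call without the 2 h replicate 1 array. Beyond the clock list their cause was not tested.

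For 7 named genes every array of 1 time lay opposite to those of the other, and the opposition itself was not tested. Their 6 h means, with the 2 h mean and the adjusted p of the difference, were AOS -0.29 (0.58; 0.388), NUC-L1 0.18 (-0.58; 0.427), DFR -0.13 (0.90; 0.372), PPT2 -2.72 (0.55; 0.307), FKF1 1.75 (-0.35; 0.307), PRR9 -1.34 (0.22; 0.307) and RCA -0.95 (0.12; 0.355). For DFR the control is dim at 2 h, so its 2 h value is a lower bound.

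Of 2522 probes with no locus code, 91 were at least 2-fold from control on both 6 h arrays the same way (67 higher, 24 lower), which is 3.61%. Of 591 probes with several loci 37 were (25 higher, 12 lower), which is 6.26%, against 6.27% of tested genes. These probes were not tested.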

How the results depend on the processing

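The 6 h count of 133 was 331 with normexp offset 10, 24 with no background correction, 665 with the scanner ratios, 657 with the series value table, 6110 with median centring, 107 with no filter, 61 with the strict filter, 162 with the mean of probes and 0 with eBayes trend. It was 5334 with each time alone, 693 with the replicate block, 812 with separate channels and 0 at adjusted p below 0.01. Leaving out an array gave 0 to 5334 at 6 h, with 0 without either 6 h array and 5334 without either 2 h array, and 0 to 276 at 2 h. A lone array is there assumed to vary like the other group. The unlike 2 h replicates widen the pooled variance. With median centring 88.3% of the called genes were higher, against 70.7% of the 133, 83.3% with no background correction, 60.2% with the replicate block and 2667 higher beside 2667 lower with each time alone or without either 2 h array, and the median gene lay at 0.33 at 2 h and 0.29 at 6 h. Aquantile between arrays leaves the ratios as they were and moves nothing. The 6 h minus 2 h count was 166 with separate channels. Separate channels and the exchanged 2 h controls were chosen after the data were seen. With the controls exchanged, the counts were 35 at 2 h, 7633 at 6 h (51.2% higher) and 321 for the difference. Arrays of the same number are taken to share a control RNA. Deviations of same-numbered samples correlated at only r = 0.0472 in the ratios, and inversely in the Cy5 levels, at r = -0.662. The labels name no other shared source, so the block stays an alternative. With it, genes without a call in the fit reported were called at 6 h, among them UGT75B1 (adjusted p = 0.00989), OPR1 (0.0146), ATAF1 (0.0352), ALDH7B4 (0.0225), DHAR2 (0.0247), CAT1 (0.0343), RVE1 (0.0155) and RVE8 (0.0204), and the 2 h root-marker list was not (0.057).

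Genes 2-fold in both replicates were 500 at 2 h and 2301 at 6 h with the scanner ratios, 497 and 2294 with the series value table, and 342 and 2141 with median centring. The correlation of the times was 0.0366 without 2 h replicate 2 and up to 0.647 when another array was left out.

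List shifts called with an estimated correlation were 0 at 2 h, 0 at 6 h and 0 for the difference. At 6 h median centring gave 17. The replicate block gave 12 at 2 h, 15 at 6 h and 13 for the difference, against 8, 11 and 9 in the fit reported. Leaving out an array gave 10 to 17 at 2 h and 11 to 16 for the difference. The oxidative stress list turned to -0.25 without the 2 h replicate 2 array (adjusted p = 0.107) and was 1.54 without replicate 1. Called lists kept their call in 468 comparisons with a setting, lost it in 54, and turned in both the test's direction and the sign of the median in 1. With median centring the medians of the nucleolus and root lists at 2 h and the photosynthesis list at 6 h changed sign while the test kept its direction. Called named genes kept it in 387 and lost it in 137, always with the same direction. The cause of these differences was not tested.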

Other observations

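The tests of the families below were planned before their values were seen, but the members of the proteasome and autophagy families were corrected after their values were seen.

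Genes for the proteasome were higher at 6 h. The median log2 ratio of 36 subunit genes was 0.852 (1.00 and 0.75 by replicate), with 35 above control on both arrays and 1 below. A first list by symbol alone, of 38 genes, also held genes of other function that carry the same symbols, and missed some subunits (median 0.788). PBB2, RPT5B and PAA2 were called over all genes, and adjusted over the list alone 32 were higher and 0 lower. The family passed with the preset correlation (adjusted p = 3.00e-16) and not with an estimated correlation (adjusted p = 0.420), so the prediction of a rise stays open. The test with the estimated correlation has only 2 residual df, so its result does not argue against a rise. At 2 h the median was 0.02.

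Ribosomal protein genes were lower at 6 h, with a median of -0.409 over 347 genes, 264 below control on both arrays and 38 above (adjusted p = 4.94e-12, and adjusted p = 0.420 with an estimated correlation). No member was lower adjusted over the list alone, and the only one called over all genes, SAG24, rose (3.61, adjusted p = 0.0490). At 2 h the replicate medians went opposite ways (0.0921 and -0.283), with 92 genes below control on both arrays and 43 above (adjusted p = 0.000172, and adjusted p = 0.972 with an estimated correlation). Autophagy genes had a median of 0.332 over 18 genes at 6 h, with 16 above control on both arrays (adjusted p = 0.000449, and adjusted p = 0.420 with an estimated correlation). With genes of other function caught by their symbols, the median was 0.305 over 29 genes and then 0.317 over 19. Both predictions stay open for the same reason.

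Of the reference-gene list, UBQ10 stood at 2.07 at 2 h (adjusted p = 0.6001) and 1.38 at 6 h (adjusted p = 0.0643), without a call. It was at least 2-fold above control on all 4 arrays, as read on the brightest of its 7 probes. UBQ3, which is not on the list, rose at 6 h (2.35, adjusted p = 0.0465). In the reference-gene list as a whole the median was 0.07 at 2 h (adjusted p = 0.134) and 0.21 at 6 h (adjusted p = 0.0968). These genes were picked after their values were seen.

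The xenobiotic, glutathione S-transferase and sulfate lists were called higher at both times with the preset correlation only (with an estimated correlation, adjusted p = 0.907 at 2 h and 0.731 at 6 h), and the glutathione S-transferases at 2 h not without the replicate 2 array (adjusted p = 0.107). APR3, GSTU2 and SAG13 were at least 2-fold above control on all 4 arrays. An untreated time course and a dye swap would part cyanamide from the other causes.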
